A study of Sus scrofa with 12 samples.

How the data were processed

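Gene expression was measured in the injected biceps femoris muscle and the draining internal iliac lymph node of 6 pigs, 3 given ISCOM-Matrix and 3 given saline, 24 hours before the tissues were taken. Per the labels' protocols, the samples were kept in RNAlater, RNA was extracted with Trizol and purified on a column kit, and biotin-labelled cRNA was made from 250 ng of total RNA for a 3' array. The deposited values are log2 expression values, per the labels of 12 arrays, and the submitters' processing notes name RMA and limma without a version, a role or an order. The values bore out the log2 scale in their range. The median of each array lay between 6.38 and 6.41 in muscle and between 6.89 and 6.91 in lymph node, and the tissues' values carried different numbers of decimals, so each tissue appears to have been normalized by the authors on its own. Levels were therefore not compared between tissues, and only changes within a tissue and differences between those changes were used. The study's design states that the pigs were sorted before treatment and kept separate, which leaves open whether adjuvant and saline pigs were housed apart, and any such effect could not be separated from the treatment.

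All 24123 probe sets of the deposited table were read. The 124 control probe sets of the array were left out of the tests and used for the quality values, which left 23999 tested, with no filter on level. Gene symbols came from the array's annotation table: 10069 probe sets had 1 symbol, 198 had several and 13732 had none. Of the 10069, 9961 matched the pig gene table (assembly Sscrofa11.1) by gene identifier and took its current symbol, and no coordinates were used. The result was 6765 genes. Probe sets with several symbols or none entered the counts and were not named.

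Groups were taken from the labels. Each tissue was tested on its own 6 arrays with limma 3.58.1 in R 4.3.3 (linear model, moderated test with empirical Bayes variances, Benjamini-Hochberg adjustment over all probe sets, threshold adjusted p under 0.05). The difference between tissues was the contrast of the pair of treatment effects in a fit of all 12 arrays with 4 group means and no pig block. The labels give each pig's arrays the same pig number. As a check of this pairing, the deviations of a pig's arrays from their group means were correlated across tissues: r lay between 0.0645 and 0.174, and the pig's own array was the best match within its treatment group in all pigs except pig 2. In the blocked fit the consensus correlation of a pig's arrays was 0.106. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

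For gene lists, 29 lists with 602 genes were fixed, of which 381 were measured, 8 of them under a renamed symbol. Lists with at least 5 measured genes were tested, which left out the list of mast cell and eosinophil markers. Each gene was represented by its probe set with the highest mean over all arrays. The test was camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 28 lists, and camera with an estimated correlation and fry were alternatives. With an estimated correlation none of the 16 muscle calls and none of the 12 lymph node calls passed, where fry, which asks whether a list's genes move one way and does not compare them with other genes, called 12 and 5. Members were counted over all probe sets and adjusted over the list alone. The list test of the difference between tissues with its alternatives, and the marker sets and tests that weigh explanations for 3 patterns (slow-fibre genes, resident macrophage genes and the interferon genes of pig 1), were added after the results were seen. All other tests, the 29 lists and the rule for named genes were fixed before the data were examined.

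Named genes followed this rule. In each tissue, among probe sets that passed, paired with 1 symbol and had all 3 adjuvant values above or all below the 3 saline values, the 12 genes with the largest rise and the 12 with the largest fall were named, each by its probe set with the smallest p. Of the 12 largest falls in muscle, 1 gene is not reported in the text here. For the difference between tissues the 10 genes with the smallest p were named. For each list up to 4 members that passed were named by size of change, and where none passed up to 2 members with the highest mean. Genes whose probe sets disagreed in direction are said to. Standard errors and adjusted p values are those of limma, and means and SDs are over 3 pigs. With 3 pigs against 3 an exact permutation test cannot go below 0.10, so no single gene was tested that way.

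The procedure was tested on simulated data with the design and number of probe sets of the series, in which 200 probe sets were moved per tissue. In muscle it recovered 39% of probe sets moved by 1 log2 unit and 83% of those moved by 2, with 6 false calls. In lymph node it recovered 75% and 95%, with 11 false calls. For the difference it recovered 49.5% and 88%, with 24 false calls. The list that was moved was called in both tissues, with 1 other of the 28 lists called in muscle and 0 in lymph node. The simulated probe sets varied independently of each other, so the list test was not tried on correlated genes. In the series the estimated correlation within a list reached 0.89, for type I interferon-stimulated genes in muscle.

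Array quality was read from medians, control probe sets for the 3' and 5' ends of transcripts, pairwise correlation and principal components, where the first component held 58.3% of the variance in muscle and 54% in lymph node. Alternatives were a filter on weakly expressed probe sets (a share of 0.333 with the lowest means is dropped), centring each array on its median, repeating quantile normalization within each tissue, 1 probe set per gene, a variance prior with a trend, a robust prior, array weights, a 2-fold minimum, fits of all 12 arrays with and without the pig as a block, other choices in the list test, and leaving out each pig in turn. Where a pig was left out, 1 treatment group kept 2 arrays per tissue. The 10 ways to split the 6 pigs into 3 and 3 were also run.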

Results

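RNA from the injected thigh muscle (biceps femoris) and from the internal iliac lymph node that drains it was measured on 12 porcine Affymetrix 3' expression arrays. The tissues came from 6 castrated male Yorkshire x Landrace pigs aged 11 weeks, taken 24 hours after an injection into the muscle. Pigs 1 to 3 received ISCOM-Matrix in 1 ml of saline, and pigs 4 to 6 received saline alone. The titles name the adjuvant ISCOM-Matrix and the source descriptions of the same arrays name it Matrix M, and the first name is used. ISCOM-Matrix is a vaccine adjuvant made of saponin, cholesterol and phospholipid without an antigen. Each pig gave 1 muscle array and 1 lymph node array, so each of the 4 groups held 3 arrays, and the number of arrays limits the precision of every value. Values are log2 expression as deposited, and changes are adjuvant minus saline on that scale. The correlation between pairs of arrays ran from 0.929 to 0.991 in muscle and from 0.979 to 0.996 in lymph node. The muscle array of pig 3 stood apart in the array's own degradation controls: its beta-actin probes at the 3' end exceeded those at the 5' end by 4.54 log2 units, against 2.96 to 3.29 on the other muscle arrays. In muscle that difference was higher in every adjuvant pig (3.28 to 4.54) than in every saline pig (2.96 to 3.26), though in pigs 1 and 2 only by a small margin. In lymph node that difference was lower in every adjuvant pig (2.42 to 2.76) than in every saline pig (2.78 to 3.02), and so was the 28S ribosomal RNA control (at most 11.54 against at least 11.57). For the array's GAPDH and EF1A controls the 3' to 5' differences overlapped between treatments in both tissues.

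The first comparison asked what the adjuvant did to gene expression in the injected muscle. The largest rise was that of SPP1 (osteopontin, a secreted phosphoprotein made by macrophages and in wounds). It stood at 13.52 ± 0.29 log2 units after adjuvant and at 6.40 ± 1.11 after saline (mean ± SD, n = 3 pigs each), a 139-fold rise with a log2 change of 7.12 (SE 0.50, limma adjusted p = 0.0023). ANKRD1, a stress-responsive ankyrin repeat protein of striated muscle, rose 19.4-fold from 8.90 ± 0.96 to 13.18 ± 0.37 (log2 change 4.27, SE 0.45, adjusted p = 0.00915). TIMP1, an inhibitor of matrix metalloproteinases, rose 9.69-fold from 8.27 ± 0.30 to 11.55 ± 0.07 (adjusted p = 0.00191). The largest fall was that of PLN (phospholamban, the regulator of the calcium pump of slow muscle and heart), from 11.21 ± 1.04 to 7.31 ± 0.92 (log2 change −3.90, SE 0.61, adjusted p = 0.0233).

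In muscle, 953 of 23999 probe sets changed at an adjusted p under 0.05, of which 656 rose and 297 fell, and 572 changed at least 2-fold. The share of rises varied with the fit. With all 12 arrays and the pig as a block 1739 rose and 1584 fell, without pig 2 390 and 304, and without pig 4 34 and 1. The adjuvant and saline values did not overlap in 26.3% of all probe sets, where chance gives 10%, and in each of the 953. The other large rises were those of CCR1, a receptor for inflammatory chemokines on myeloid cells (log2 change 4.08), GPNMB, a glycoprotein of macrophages (3.82), C1H15orf48 (3.69), and CCL2, the monocyte-attracting chemokine (3.62). LGALS3 (galectin-3, log2 change 3.58), PTGDS (a prostaglandin D synthase, 3.37), RARRES1 (3.35), CCL19 (a ligand of CCR7, 3.16) and SLC11A1 (a metal transporter of phagosomes, 3.10) also rose. Their adjusted p values lay between 0.0023 for SLC11A1 and 0.0297 for CCL2. Other large falls were those of VEGFA, the angiogenic growth factor (log2 change −2.62), DKK2, a Wnt pathway regulator (−2.61), PPARGC1A, a coactivator of mitochondrial biogenesis (−2.55), and GOT1, an aspartate aminotransferase (−2.46). SNTB1 (a syntrophin of the dystrophin complex, log2 change −2.42), TRNP1 (−2.35), TP53INP2 (−2.33), PPP1R3B (a glycogen-targeting phosphatase subunit, −2.05), MYL3 (the slow-fibre myosin light chain, −1.99) and RAB3A (−1.88) fell as well. Their adjusted p values lay between 0.0178 for GOT1 and TP53INP2 and 0.0482 for DKK2.

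**Figure D1:**
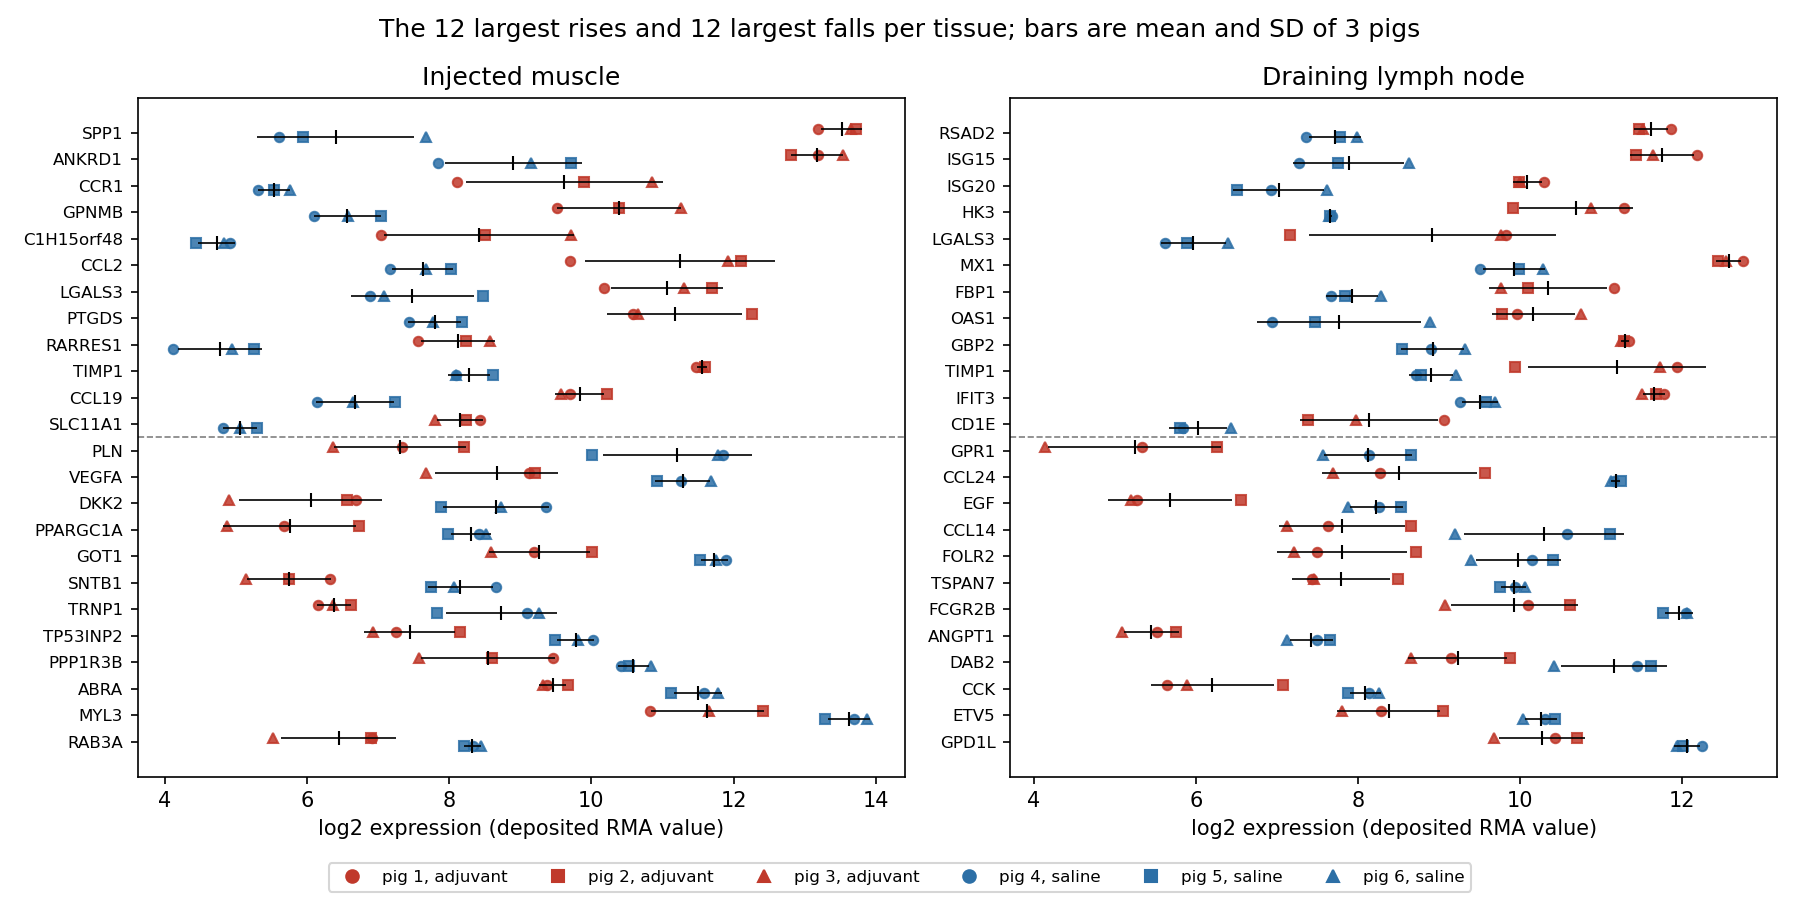
Log2 expression of the 12 genes with the largest rise (above the dashed line) and the 12 with the largest fall (below it) in each tissue, 1 point per pig, with the mean and SD of the 3 pigs of each treatment in black. In muscle SPP1 stood at 13.52 after adjuvant against 6.40 after saline, and in lymph node RSAD2 stood at 11.61 against 7.71.

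Genes of innate sensing and inflammation rose as groups in muscle by camera, a test of a list against all other genes that was run with a preset correlation between genes. Of 14 measured genes for pattern recognition and adaptors, 4 rose and none fell, and 6 rose when adjusted over the list alone (list median log2 change 0.41, camera adjusted p = 0.000586, adjusted p = 0.479 with an estimated correlation). They were TLR2 (log2 change 3.09, adjusted p = 0.0181), a receptor for bacterial lipoproteins, CASP1 (2.84, adjusted p = 0.0188), the inflammasome protease, and TLR4 (2.58, adjusted p = 0.00761) and LY96 (2.57, adjusted p = 0.0307), which together bind lipopolysaccharide. Of 18 chemokine ligands, 4 rose, namely CCL2, CCL19, CXCL16 (log2 change 2.01) and AMCF-II (0.97), the porcine alveolar macrophage neutrophil chemoattractant. Adjusted over the list alone, 6 chemokines rose and 1 fell (median 0.91, camera adjusted p = 0.00576, adjusted p = 0.351 with an estimated correlation). Pig 1 stood lower than the other adjuvant pigs against the saline mean, with medians of 0.15, 0.99 and 1.04 in pigs 1, 2 and 3 for chemokine ligands. Of 12 genes for apoptosis and lytic cell death, 5 rose, among them CASP1, the TNF receptors TNFRSF1B (log2 change 1.28) and TNFRSF1A (1.11), and BID (1.27), a pro-apoptotic BCL2 family member. Adjusted over the list alone, 8 rose (median 0.80, camera adjusted p = 0.000311, adjusted p = 0.479 with an estimated correlation), and the medians of pigs 1, 2 and 3 were 0.21, 0.88 and 1.11. Of 6 genes of the NF-kappaB pathway, PTX3 (a long pentraxin, log2 change 2.88) rose, with 2 adjusted over the list alone. The pathway was called as a list (median 0.33, camera adjusted p = 0.0188, adjusted p = 0.479 with an estimated correlation), and not without pig 2 (adjusted p = 0.061), with medians of 0.08, 0.45 and 0.46 in pigs 1, 2 and 3. The list of inflammatory cytokines also held IL10 and TGFB1, which can restrain inflammation. Of its 15 measured genes, 3 rose, both over all probe sets and adjusted over the list alone: IL18 (log2 change 1.95), IL10 (1.28, from a low 4.42 to 5.70) and TGFB1 (0.93). That list lay just under the threshold (median 0.22, camera adjusted p = 0.0497, adjusted p = 0.715 with an estimated correlation), with medians of −0.07, 0.18 and 0.59 in pigs 1 to 3. Its adjusted p was 0.518 without pig 3, 0.131 without pig 5, 0.0618 after quantile normalization within the tissue was repeated and 0.106 in the fit of all 12 arrays with the pig as a block.

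The 24 measured type I interferon-stimulated genes, which respond to antiviral interferons, had a median log2 change of 1.85 in muscle and rose as a list (camera adjusted p = 7.95e-07, adjusted p = 0.501 with an estimated correlation). None of the 24 passed over all probe sets in limma, where 4950 probe sets had an unadjusted p under 0.05, and 19 rose when adjusted over the list alone. Of the pair with the highest means, IFIT3 stood at 10.89 ± 2.43 after adjuvant and 7.67 ± 0.45 after saline (adjusted p = 0.145), and IFI44L at 11.04 ± 1.26 and 9.19 ± 0.03 (adjusted p = 0.114). Without pig 1 both passed (IFIT3 log2 change 4.62, adjusted p = 0.00152, IFI44L 2.58, adjusted p = 0.00118), and in the fit of all 12 arrays with the pig as a block too (adjusted p = 0.0272 and 0.0168). The spread lay between pigs: against the saline mean the list's median was 0.23 in pig 1, 2.80 in pig 2 and 2.59 in pig 3, and from −0.12 to 0.01 in the saline pigs. Of 10 interferon-gamma-induced genes, IRF8 rose, a transcription factor of myeloid cells (log2 change 1.57, adjusted p = 0.00473), and 7 rose when adjusted over the list alone. That list was called too (median 1.04, camera adjusted p = 0.000322, adjusted p = 0.479 with an estimated correlation), and pig 1 stood lower in it as well (interferon-gamma-induced genes 0.26, 1.13 and 1.65 in pigs 1, 2 and 3). Of 24 genes for antigen processing and presentation, 8 rose and 15 rose when adjusted over the list alone. They rose as a list (median 0.94, camera adjusted p = 6.36e-08, adjusted p = 0.474 with an estimated correlation), with medians of 0.40, 1.20 and 0.96 in pigs 1 to 3. Among the 8 were CTSS (log2 change 2.44), the cathepsin that degrades the invariant chain, PSMB8 (1.80), an immunoproteasome subunit, and PDIA3 (1.54), a disulfide isomerase of the peptide-loading complex. SLA-DMA, which helps to load peptide onto class II molecules, rose by its better probe set (1.15), while its other probe set stood at −0.31 and did not pass. Of 16 complement genes, 5 rose and 9 rose when adjusted over the list alone. The complement list rose (median 0.97, camera adjusted p = 0.000472, adjusted p = 0.351 with an estimated correlation). They included the complement regulators CD55 (log2 change 1.92) and CD46 (1.91), and the classical pathway components C4A (1.83) and C1S (1.52).

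Among the leukocyte lists in muscle, 8 of 17 monocyte and macrophage markers rose and 9 rose when adjusted over the list alone. The list rose (median log2 change 0.63, camera adjusted p = 4.05e-05, adjusted p = 0.297 with an estimated correlation). The largest were TYROBP (2.49), a signalling adaptor of myeloid and NK cells, CTSS (2.44), AIF1 (2.37), an actin-binding protein of macrophages, and LGMN (2.14), a lysosomal protease. Of 9 dendritic cell markers, CD1.1, a lipid-presenting molecule (log2 change 1.95), and IRF8 rose, with 4 adjusted over the list alone. The list rose (median 0.36, camera adjusted p = 0.015, adjusted p = 0.428 with an estimated correlation). Of 5 B cell and plasma cell markers, 2 rose and 3 rose when adjusted over the list alone. As a list they rose (median 1.01, camera adjusted p = 0.0205, adjusted p = 0.479 with an estimated correlation), though not without pig 3 (adjusted p = 0.104). The pair was BLNK (log2 change 2.58, adjusted p = 0.00365), an adaptor of B cell receptor signalling that macrophages also express, and XBP1 (0.82, adjusted p = 0.0244), a transcription factor of the unfolded protein response in secretory cells. None of 11 neutrophil markers passed in limma, at either adjustment (median 0.14, camera adjusted p = 0.341). Log2 changes were 0.53 for NCF1 (adjusted p = 0.187) and 0.14 for PR39 (adjusted p = 0.766), whose other probe set stood at −0.01. In the fit of all 12 arrays with the pig as a block NCF1 passed (adjusted p = 0.0449). None of 16 T cell markers passed (median 0.18, camera adjusted p = 0.424), but without pig 1 the T cell markers were called higher as a list (adjusted p = 0.0166). CD2 stood at 7.16 ± 1.41 after adjuvant and 5.95 ± 0.11 after saline (adjusted p = 0.334), with CD3D at 0.33 (adjusted p = 0.406). Without pig 1 CD2 passed (2.03, adjusted p = 0.00192). None of 7 NK and cytotoxic cell markers passed (median −0.05, mean 0.07, camera direction down, adjusted p = 0.841), with log2 changes of −0.23 for GNLY and 0.62 for GZMH. None of 7 red cell and platelet markers passed (median −0.01, mean 0.09, camera direction up, adjusted p = 0.955), among them HBB (−0.36) and GP9 (0.04). Of the mast cell and eosinophil list 3 genes were measured, too few for the list test, and neither MS4A2 (1.75, adjusted p = 0.115) nor KIT (0.24, adjusted p = 0.381) passed over all probe sets. MS4A2, a chain of the IgE receptor, was the 1 gene that rose when adjusted over the list alone. It also passed without pig 2 (adjusted p = 0.0453), with array weights (0.0305) and in that fit of all 12 arrays (0.0209).

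Genes of mitochondrial respiration and of the contractile apparatus fell as lists in muscle, in the same arrays in which monocyte and macrophage markers rose (list median 0.63, TYROBP 2.49, AIF1 2.37). Of 18 genes of oxidative phosphorylation 6 fell and none rose, and 16 fell when adjusted over the list alone. They fell as a list (median log2 change −0.71, camera adjusted p = 6.89e-10, adjusted p = 0.351 with an estimated correlation). Besides PPARGC1A these included the succinate dehydrogenase subunits SDHA (−1.31, adjusted p = 0.0497) and SDHC (−1.14, adjusted p = 0.0443), and the complex I subunit NDUFS1 (−1.28, adjusted p = 0.035). The list's median against the saline mean was −0.76, −0.60 and −0.99 in pigs 1, 2 and 3, the last being the pig with the high 3' to 5' difference of actin. The 27 skeletal muscle contraction genes fell as a list (median −0.41, camera adjusted p = 0.000322, adjusted p = 0.497 with an estimated correlation), with per-pig medians of −0.38, −0.07 and −0.99 in pigs 1 to 3. In that list MYL3 fell and TPM3 rose over all probe sets, and 4 fell and 1 rose when adjusted over the list alone. TPM3, a tropomyosin of slow fibres and of many non-muscle cells, gave opposite calls between its probe sets, with changes of 1.51 and 1.20 (adjusted p = 0.0236) for a pair of them and −1.56 (adjusted p = 0.0216) for the last. Of 8 genes for muscle injury and regeneration ANKRD1 rose, at both adjustments (median −0.03, mean 0.52, camera direction up, adjusted p = 0.817). Of 16 glycolysis genes the glucose transporter SLC2A3 rose (log2 change 2.40), at both adjustments (median −0.10, mean 0.06, camera direction down, adjusted p = 0.667).

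**Figure D2:**
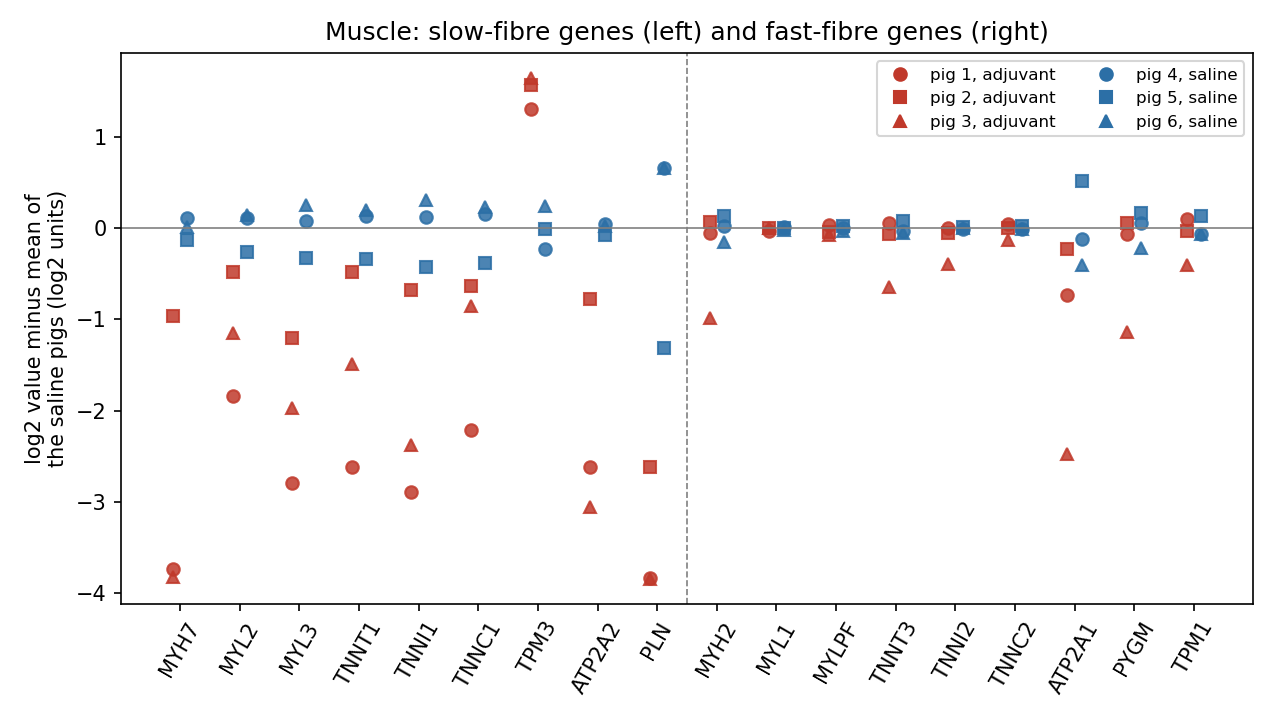
Log2 value minus the mean of the saline pigs in muscle for slow-fibre genes (left of the dashed line) and fast-fibre genes (right), 1 point per pig and gene. MYL3 fell by 1.99 on the log2 scale, and TPM3 is shown by 1 of its probe sets, which disagree in direction.

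Of 22 genes for extracellular matrix and fibroblasts, TIMP1, TNC (tenascin C, log2 change 1.88) and PLAU (urokinase, 1.45) rose, with 4 adjusted over the list alone. These genes rose as a list (median 0.34, camera adjusted p = 0.0205, adjusted p = 0.567 with an estimated correlation). That call was lost without pig 1 (adjusted p = 0.154), pig 2 (0.0737) or pig 4 (0.0707), and without weakly expressed probe sets (0.0738), and the list's median was 0.62, 0.47 and −0.02 in pigs 1, 2 and 3. Of 22 genes of heat shock and stress response, HMOX1 (heme oxygenase, log2 change 2.02) and HSP90B1 (a chaperone of the endoplasmic reticulum, 1.09) rose. There were 6 rises when adjusted over the list alone (median 0.34, camera adjusted p = 0.0246, adjusted p = 0.501 with an estimated correlation), with medians of 0.10, 0.57 and 0.50 in pigs 1 to 3. The list call was lost without pig 2 (adjusted p = 0.168) or pig 6 (0.0689), and with the mean of a gene's probe sets (0.0605). Of 16 genes of endothelium and adhesion, VCAM1 (log2 change 2.00), SELE (1.25) and SELP (0.68), adhesion molecules of activated vessels, rose, with 5 adjusted over the list alone. The list itself was not called, with a median of −0.13, a mean of 0.19 and a camera direction up (adjusted p = 0.841). CCL19 was the 1 of 7 lymph node stroma genes that rose, at both adjustments (median 0.18, camera adjusted p = 0.424). Of 19 cell cycle genes the replication helicase subunits MCM2 (0.91) and MCM5 (0.84) rose, at both adjustments (median 0.09, camera adjusted p = 0.144), with the other MCM2 probe sets at 0.06 and −0.003. The cell cycle list was called higher without pig 3 (adjusted p = 0.00454) or pig 5 (0.0498). None of 10 adipocyte markers passed (median −0.13, camera adjusted p = 0.41), with FABP4 at 0.14 and SCD at −0.27. None of 11 genes of cholesterol synthesis and uptake passed over all probe sets, with 1 adjusted over the list alone (median 0.19, camera adjusted p = 0.667, FDFT1 −0.45, INSIG1 −0.10). Of 7 reference genes ACTB (1.28) and PPIA (0.77) rose and SDHA fell, with 4 higher and 1 lower adjusted over the list alone (median 0.50, camera adjusted p = 0.0711). The reference genes were called higher as a list without pig 3 (adjusted p = 0.0498).

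The muscle count fell most when a saline pig was left out, to 35 without pig 4, 57 without pig 6 and 344 without pig 5. The fit pools the spread of both treatments, and adjuvant muscle arrays correlated less within their group (mean r 0.972) than saline ones (0.987). Leaving out a saline pig gives the adjuvant arrays more weight in that spread, and the cause of the losses was not tested. The muscle count was 2402 with array weights and 3323 when all 12 arrays were fitted with the pig as a block. Of the 68 named genes that changed in muscle, SPP1, TIMP1, CCL19, SLC11A1, IRF8 and BLNK passed without any 1 pig. Without pig 4, 60 of these 68 genes lost their call, 57 without pig 6, 36 without pig 5, 17 without pig 2, 10 without pig 1 and 6 without pig 3.

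The second comparison asked the same of the draining lymph node. RSAD2 (viperin, an antiviral enzyme) rose most, 15-fold, from 7.71 ± 0.32 after saline to 11.61 ± 0.21 after adjuvant (n = 3 pigs each, log2 change 3.90, SE 0.18, adjusted p = 0.00113). ISG15, a ubiquitin-like protein induced by interferon, rose 14.6-fold from 7.88 ± 0.68 to 11.75 ± 0.39 (log2 change 3.87, SE 0.34, adjusted p = 0.00384). HK3, a hexokinase of myeloid cells, rose 8.19-fold from 7.66 ± 0.02 to 10.69 ± 0.70 (log2 change 3.03, adjusted p = 0.00545). The largest falls were those of GPR1, a chemerin receptor, from 8.12 ± 0.54 to 5.24 ± 1.06 (log2 change −2.88, SE 0.51, adjusted p = 0.0255), and of CCL24. This eosinophil-attracting chemokine fell from 11.18 ± 0.06 to 8.51 ± 0.96 (−2.67, SE 0.41, adjusted p = 0.0185).

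In lymph node, 1271 of 23999 probe sets changed, of which 367 rose and 904 fell, and 364 changed at least 2-fold. The excess of falls was smaller with 1 probe set per gene, where 234 rose and 291 fell. Without pig 4, 64 rose and 77 fell. The actin 3' to 5' difference moved with treatment in lymph node too, in the opposite direction to muscle (at most 2.76 after adjuvant and at least 2.78 after saline), while those of GAPDH and EF1A overlapped between treatments. The adjuvant and saline values did not overlap in 27% of all probe sets, where chance gives 10%, and in each of the 1271. Further large rises were those of ISG20 (an interferon-induced exonuclease, log2 change 3.07), LGALS3 (2.95), MX1 (an antiviral GTPase, 2.65), FBP1 (a gluconeogenic enzyme, 2.41), OAS1 (an antiviral oligoadenylate synthetase, 2.40), GBP2 (a guanylate-binding protein, 2.37), TIMP1 (4.91-fold), IFIT3 (2.15) and CD1E (2.11). Their adjusted p values lay between 0.00228 for MX1 and 0.0498 for LGALS3. Further large falls were those of EGF (log2 change −2.55), CCL14 (−2.49), the folate receptor of macrophages FOLR2 (−2.17), TSPAN7 (−2.13), the inhibitory Fc receptor FCGR2B (−2.03), the vessel-stabilising ligand ANGPT1 (−1.98), the endocytic adaptor DAB2 (−1.93), CCK (−1.89), ETV5 (−1.88) and GPD1L (−1.79). Their adjusted p values lay between 0.00544 for ANGPT1 and 0.0424 for CCL14.

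Interferon-stimulated genes rose together in lymph node. Of 24 measured type I interferon-stimulated genes 22 rose and 24 rose when adjusted over the list alone. The list as a whole rose (median log2 change 1.71, camera adjusted p = 1.55e-25, adjusted p = 0.264 with an estimated correlation). RSAD2, ISG15, ISG20 and IFIT1 (2.74), an inhibitor of viral translation, rose most. The list's median against the saline mean was 1.84, 1.59 and 1.70 in pigs 1, 2 and 3, and from −0.10 to 0.19 in the saline pigs. Of 10 interferon-gamma-induced genes 7 rose and 8 rose when adjusted over the list alone. This list rose too (median 1.28, camera adjusted p = 6.45e-07, adjusted p = 0.402 with an estimated correlation). They were led by GBP2, the tryptophanyl-tRNA synthetase WARS (1.80), GBP1 (1.56) and SOCS1 (1.39), a feedback inhibitor of cytokine signalling. Of 24 genes for antigen processing and presentation 7 rose and 15 rose when adjusted over the list alone. They too rose as a list (median 0.42, camera adjusted p = 2.67e-06, adjusted p = 0.509 with an estimated correlation). These included the peptide transporter TAP1 (1.11), the proteasome genes PSMB10 (2.14-fold) and PSME2 (0.95), and CIITA (0.79), the transactivator of class II genes.

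**Figure D3:**
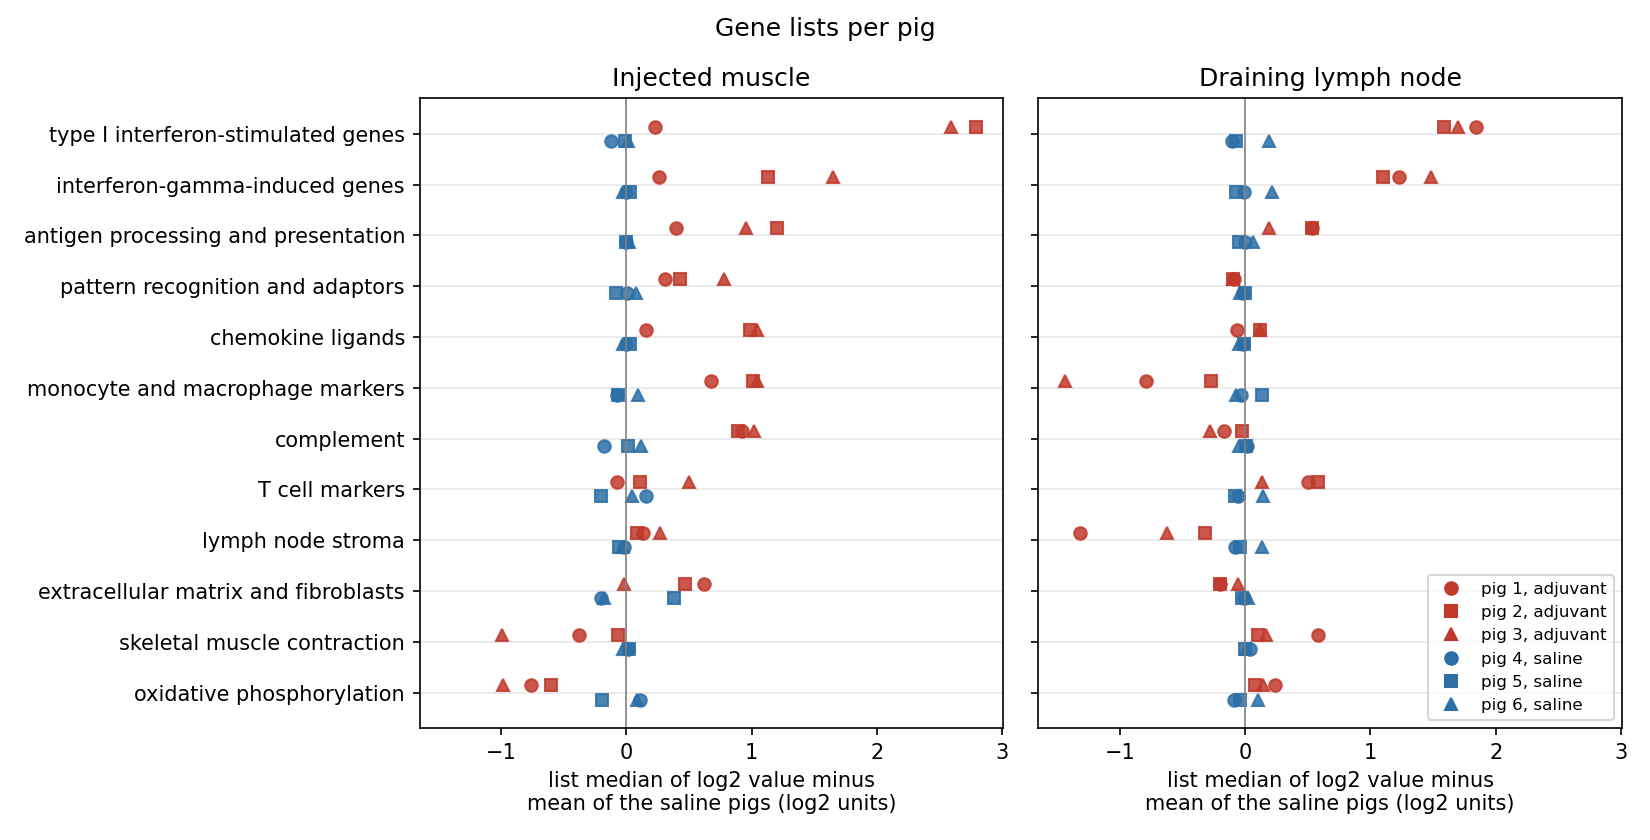
Median over each of 12 gene lists of the log2 value minus the mean of the saline pigs, 1 point per pig, in muscle and in lymph node. For type I interferon-stimulated genes pig 1 stood at 0.23 in muscle against 2.80 and 2.59 in pigs 2 and 3, and at 1.84 in lymph node against 1.59 and 1.70.

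Inflammatory genes were mixed in lymph node. Of 15 genes in the list of inflammatory cytokines IL1B (log2 change 1.44), IL6 (0.74) and TGFB1 (0.64) rose and IL18 fell (−1.36), with 9 higher and 2 lower adjusted over the list alone. The cytokine list rose (median 0.37, camera adjusted p = 0.0291, adjusted p = 0.402 with an estimated correlation). That call was lost without pig 2 (adjusted p = 0.0876), without pig 6 (0.111), without weakly expressed probe sets (0.237) and when quantile normalization was repeated (0.0505). Of 14 genes for pattern recognition CASP1 rose (1.45) and TLR4 (−1.36), TLR2 (−0.88) and TLR6 (−0.72) fell, the same numbers as adjusted over the list alone (median −0.08, camera adjusted p = 0.152). Of 12 genes for apoptosis and lytic cell death CASP1 and BID (0.54) rose, with 3 higher and 1 lower adjusted over the list alone. The cell death list rose (median 0.24, camera adjusted p = 0.0491, adjusted p = 0.402 with an estimated correlation). That list did not pass without pig 1 (adjusted p = 0.0714), pig 2 (0.0777) or pig 6 (0.109). Neither did it pass in the fit of all 12 arrays with the pig as a block (0.097), with repeated quantile normalization (0.063), with the mean of a gene's probe sets (0.0744) or without weakly expressed probe sets (0.225). Of 18 chemokine ligands none rose and CCL24 and AMCF-II fell, with 5 higher and 5 lower adjusted over the list alone (median 0.02, mean 0.02, camera direction down, adjusted p = 0.563). AMCF-II fell by 1 probe set (−0.47, adjusted p = 0.0257), while its other probe sets stood at 1.21 and 1.33 and did not pass. None of 6 NF-kappaB pathway genes passed at either adjustment (median 0.34, camera adjusted p = 0.469, NFKBIA −0.26, SOD2 0.42).

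Among the leukocyte lists in lymph node, the 17 monocyte and macrophage markers fell as a list (median log2 change −0.74, camera adjusted p = 0.0033, adjusted p = 0.541 with an estimated correlation). By the probe set used for each gene, none of them fell when adjusted over all probe sets, though VSIG4 passed as lower by its other probe sets. FCGR1A, the high-affinity IgG receptor that interferon-gamma induces, rose (1.11, adjusted p = 0.00295). Adjusted over the list alone 9 fell and 1 rose. The list's median was −0.79, −0.28 and −1.44 in pigs 1, 2 and 3. The 16 T cell markers rose as a list (median 0.37, camera adjusted p = 0.00661, adjusted p = 0.541 with an estimated correlation, and adjusted p = 0.0599 without pig 2). In it CD2, an adhesion receptor (1.05), and CD8A (0.60) rose and CD4 fell (−0.44), with 5 higher and 1 lower adjusted over the list alone. Of 7 NK and cytotoxic cell markers the granzyme GZMH rose (1.23), with 2 adjusted over the list alone. The list rose as well (median 0.19, camera adjusted p = 0.039, adjusted p = 0.509 with an estimated correlation). That list did not pass without pig 1 (adjusted p = 0.0667), pig 2 (0.0777), pig 5 (0.129) or pig 6 (0.0514). It also failed with repeated quantile normalization (0.0597), with the mean of a gene's probe sets (0.0584) or without weakly expressed probe sets (0.147). Of 5 B cell and plasma cell markers CD38, an ectoenzyme of activated lymphocytes, rose (1.07), at both adjustments (median −0.11, mean 0.15, camera direction up, adjusted p = 0.962). Of 11 neutrophil markers the myeloid receptor TREM1 rose (0.78), at both adjustments (median 0.18, camera adjusted p = 0.0703), and the neutrophil markers were called higher as a list without pig 4 (adjusted p = 0.0173) or pig 5 (0.0478). Of 9 dendritic cell markers the maturation marker CD83 rose (0.53), with 2 higher and 1 lower adjusted over the list alone (median 0.11, camera adjusted p = 0.215). None of 7 red cell and platelet markers passed (median 0.32, camera adjusted p = 0.103, HBB 0.10, GP9 0.26). Neither CCR3 (1.36, adjusted p = 0.257) nor MS4A2 (0.48, adjusted p = 0.258) of the 3 mast cell and eosinophil genes passed.

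Genes of endothelium and of complement fell as lists in lymph node. Of 16 genes of endothelium and adhesion CDH5, the cadherin of endothelial junctions, fell (−0.51), with 6 lower and 1 higher adjusted over the list alone. The list fell (median −0.19, camera adjusted p = 0.0325, adjusted p = 0.402 with an estimated correlation). That call was lost without pig 1 (adjusted p = 0.0667), with the mean of a gene's probe sets (0.0584) and without weakly expressed probe sets (0.158). Of 16 complement genes CFD (complement factor D) fell (−1.27), at both adjustments (median −0.16, camera adjusted p = 0.039, adjusted p = 0.509 with an estimated correlation). That call was lost without pig 1 (adjusted p = 0.0828), pig 3 (0.0989), pig 4 (0.079) or pig 6 (0.0514), with the mean of a gene's probe sets (0.0636) and without weakly expressed probe sets (0.158). Of 7 lymph node stroma genes PDPN (podoplanin, of lymphatic endothelium and reticular cells) fell (−1.30), with 4 lower and 2 higher adjusted over the list alone (median −0.76, camera adjusted p = 0.0647). The lymph node stroma list was called lower without pig 2 (adjusted p = 0.00364) or pig 5 (0.0478), with arrays centred (0.0493) and in the fit of all 12 arrays with the pig as a block (0.00383). Of 22 matrix genes TIMP1 and VCAN (versican, 1.42) rose and FBN1 (fibrillin, −0.49) fell, with 2 higher and 5 lower adjusted over the list alone (median −0.12, mean 0.08, camera direction down, adjusted p = 0.163). Of 10 adipocyte markers PPARG, a nuclear receptor of adipocytes and macrophages, fell (−1.44), at both adjustments (median 0.24, camera direction up, adjusted p = 0.588). Of 8 genes for muscle injury and regeneration ANKRD1 (1.73) and the cell cycle inhibitor CDKN1A (1.04) rose and IGF1 fell (−1.16), with 2 higher and 2 lower adjusted over the list alone (median 0.09, camera adjusted p = 0.962).

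The 27 skeletal muscle contraction genes rose as a list in lymph node, although none passed singly at either adjustment (median 0.32, camera adjusted p = 0.00468, adjusted p = 0.541 with an estimated correlation). The pair with the highest means, TPM3 (0.22) and TPM2 (0.35), are tropomyosins also made by non-muscle cells. The rise was not confined to such genes, since the fast-fibre genes TNNC2 (1.18), MYH2 (0.69) and MYLPF (0.58) changed more. Of the 27 changes 26 were positive, and their source was not tested. The list did not pass without pig 1 (adjusted p = 0.0667), pig 6 (0.0507) or weakly expressed probe sets (0.299), and its median was 0.58, 0.10 and 0.17 in pigs 1, 2 and 3. The 16 glycolysis genes rose as a list (median 0.18, camera adjusted p = 0.039, adjusted p = 0.541 with an estimated correlation), with none over all probe sets and 1 adjusted over the list alone (GAPDH 0.31, LDHB 0.02). That call was lost without pig 1 (adjusted p = 0.0885), pig 3 (0.0845) or pig 4 (0.0777), in the fit of all 12 arrays with the pig as a block (0.0772), with the mean of a gene's probe sets (0.0584) and without weakly expressed probe sets (0.0557). COX7A1, the muscle form of a cytochrome oxidase subunit, fell (−0.57) as the 1 of 18 genes of oxidative phosphorylation, at both adjustments (median 0.16, camera direction up, adjusted p = 0.165). The transcription factor ATF3 rose (0.96) as the 1 of 22 heat shock and stress genes, at both adjustments (median 0.09, camera adjusted p = 0.472). Of 11 genes of cholesterol synthesis and uptake FDPS rose (0.80), with 3 higher and 1 lower adjusted over the list alone (median 0.18, camera adjusted p = 0.222), and the list of cholesterol synthesis and uptake was called higher without pig 5 (adjusted p = 0.0376). None of 19 cell cycle genes passed at either adjustment (median 0.10, camera adjusted p = 0.563, PCNA 0.13, TOP2A −0.10), nor did any of 7 reference genes (median 0.15, camera adjusted p = 0.26, GAPDH 0.31, PPIA 0.09). The cell cycle list was called higher without pig 2 (adjusted p = 0.0285).

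The lymph node count was 141 without pig 4, 148 without pig 5, 197 without pig 1 and 576 without pig 3. It was 2256 with array weights, 525 with 1 probe set per gene and 545 when all 12 arrays were fitted with the pig as a block. In that blocked fit, which shares its spread with muscle, 31 named lymph node genes no longer passed, with adjusted p values from 0.0501 for LGALS3 to 0.675 for ATF3. The 15 named genes that passed without any 1 pig were RSAD2, ISG15, ISG20, MX1, GBP2, IFIT1, IFIT3, HK3, ANGPT1, CASP1, CD38, FCGR1A, IGF1, PSMB10 and TAP1. Of these, 8 did not pass in the blocked fit, namely ISG15 (adjusted p = 0.0504), CD38 (0.0833), RSAD2 (0.0889), GBP2 (0.0911), IFIT1 (0.102), PSMB10 (0.139), IFIT3 (0.261) and TAP1 (0.285). Of the 62 named genes that changed in lymph node, 47, 43, 43, 25, 20 and 3 lost their call without pigs 4, 5, 1, 3, 6 and 2.

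The third comparison tested where the change in muscle differed from the change in lymph node, as the difference between the pair of log2 changes. TLR4 rose by 2.58 in muscle and fell by 1.36 in lymph node, a difference of 3.94 (SE 0.37, adjusted p = 0.000678). GP91-PHOX, the catalytic subunit of the phagocyte NADPH oxidase, rose in muscle (adjusted p = 0.0023) and stood at −0.16 in lymph node (adjusted p = 0.529), a difference of 2.46 (SE 0.19, adjusted p = 0.000232). CYBA, its partner subunit, rose by 1.92 in muscle and stood at −0.11 in lymph node (difference 2.03, adjusted p = 0.000715). In all, 1151 of 23999 probe sets differed, of which 811 were higher in muscle than in lymph node in their change and 340 lower, and 750 differed at least 2-fold. The genes with the smallest p also included GMFG (a regulator of actin branching in leukocytes, difference 2.68), CAPG (a macrophage actin-capping protein, 2.52), the tetraspanin CD9 (2.94), BLNK (2.75), LITAF (2.15), GPX4 (a peroxidase of membrane lipids, 1.88) and RGS10 (2.16). Each of these 10 genes rose in muscle, TLR4 was the one of them that fell in lymph node, and all 10 kept their call without any 1 pig and with the pig as a block.

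The list test of the difference was added after the results were seen. The change of 17 monocyte and macrophage markers was higher in muscle (median 0.63) than in lymph node (−0.74), with a median difference of 2.18 (camera adjusted p = 3.68e-09, adjusted p = 0.203 with an estimated correlation). The change of complement genes was also higher in muscle (0.97 against −0.16, median difference 1.27, camera adjusted p = 5.29e-07, adjusted p = 0.152 with an estimated correlation). Oxidative phosphorylation (median difference −0.89, camera adjusted p = 1.28e-10, adjusted p = 0.152 with an estimated correlation) was lower in muscle than in lymph node in its change. So was skeletal muscle contraction (−1.02, camera adjusted p = 8.6e-06, adjusted p = 0.414 with an estimated correlation). For type I interferon-stimulated genes no difference was called (median difference 0.29, camera adjusted p = 0.671), but without pig 1 the list was called higher in muscle (adjusted p = 2.54e-08). Between 9 and 14 of 28 lists were called when 1 pig was left out, against 11 with all pigs.

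In the probe sets called in both tissues, 41 rose in both and 25 fell in both, where independent lists of these sizes would share 10.03 and 11.2. The tissues came from the same pigs, so differences between pigs can be shared, which these expected numbers leave out. Those that rose in both included TIMP1, LGALS3, ANKRD1, CASP1, HK3 (log2 change 2.22 in muscle and 3.03 in lymph node), CCR1 (4.08 and 0.67), IFI30 (2.24 and 0.75), a thiol reductase of antigen processing, and ANXA1 (1.77 and 0.88), a phospholipid-binding protein. These examples, IFI30 and ANXA1 among them, were chosen after their values were seen. A further 25 rose in muscle and fell in lymph node, where 24.7 would be shared, and 1, SNTB1, fell in muscle and rose in lymph node (−2.42 and 0.91), where 4.54 would be shared. TLR2 (3.09 and −0.88), IL18 (1.95 and −1.36) and AMCF-II (0.97 and −0.47) were among those called in opposite directions. Across all probe sets, which are not independent replicates, the log2 changes of the tissues correlated at r = 0.279, against 0.072 to 0.235 in the 9 other splits of the pigs into groups of 3. Those splits mix adjuvant and saline pigs, and part of the treatment contrast remains in each. The counts were lowest when a saline pig was left out: without pigs 4, 5 and 6 the differing probe sets numbered 130, 450 and 339 and the probe sets called the same way in both tissues 0, 3 and 8, against 1151 and 66 with all pigs. With array weights 2288 probe sets differed, and with 1 probe set per gene 624.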

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

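The tests of the 3 patterns weighed here and the list test of the difference between tissues were chosen only after the results were seen, while the splits of the pigs and the test of the difference for single probe sets were planned.

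The treatment effect differed between muscle and lymph node, by the test of the difference itself, for 1151 probe sets. The log2 change in muscle minus that in lymph node was 2.46 for GP91-PHOX, 2.68 for GMFG, 2.52 for CAPG, 2.94 for CD9 and 2.75 for BLNK. It was 3.94 for TLR4, 2.03 for CYBA, 2.15 for LITAF, 1.88 for GPX4 and 2.16 for RGS10. Among the 26 probe sets called in opposite directions in the tissues were those of TLR4 and of SNTB1 (difference −3.32), TLR2 (3.97), IL18 (3.31) and AMCF-II (1.44), the last with lymph node probe sets that disagreed in direction. For whole lists the test of the difference called monocyte and macrophage markers (median difference 2.18), complement (1.27), B cell and plasma cell markers (0.91), pattern recognition (0.85), lymph node stroma (0.53), apoptosis and lytic cell death (0.51), chemokine ligands (0.51), antigen processing and presentation (0.46), extracellular matrix and fibroblasts (0.32), skeletal muscle contraction (−1.02) and oxidative phosphorylation (−0.89). None of these 11 list calls passed with an estimated correlation. Without pig 3 the calls for antigen processing (adjusted p = 0.113), apoptosis (0.0632) and B cell markers (0.095) were lost. The B cell call was also lost without pig 2 (0.0638) or pig 6 (0.0558), and the matrix call without pig 1 (0.162), pig 2 (0.149), pig 4 (0.123) or pig 6 (0.0569).

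The 6 pigs can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixes adjuvant and saline pigs in both groups, so the treatment effect adds to the spread within groups and lowers the calls. The other splits therefore do not show what differences between pigs alone would give. The real split gave 953 changed probe sets in muscle, 1271 in lymph node, 1151 for the difference and 66 called the same way in both tissues, and the highest of the others was 0 in each case. For called lists the real split gave 16 in muscle, 12 in lymph node and 11 for the difference, and the highest of the others gave 17, 12 and 13. The number of splits with a result as large, the real one included, was 1 for each count of probe sets, 2 for the lists of muscle, 2 for those of lymph node and 5 for those of the difference.

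In muscle, 9 slow-fibre genes had a median of −2.62, −0.68 and −1.97 in pigs 1, 2 and 3 against the saline mean, averaging −1.76. TPM3 in the set rose. Degraded RNA in the muscle of pig 3 as the whole cause would leave pig 1 in the saline range of −0.33 to 0.23, where its slow-fibre median was −2.62. Dilution of fibre RNA by RNA of incoming cells predicts an equal fall of fast-fibre genes, and fewer slow fibres in the pieces taken predict none. Over 5 fast genes no brighter than the brightest slow gene, the slow minus fast median averaged −1.52 ± 1.01 (SD, n = 3) and the fast-fibre median −0.23 ± 0.36. However, 4 of the 5, at 14.35 to 14.67 in saline, lay within 1 log2 unit of the highest muscle value, where a fall may be hidden. The slow-fibre genes MYL2 and TNNC1, at 14.78 and 14.40, were nevertheless lower by 1.16 and 1.23, though neither passed over all probe sets. The other of the 5 fast genes, ATP2A1, stood at 11.61 in saline and was lower by 1.14, without passing over all probe sets. The slow-fibre median minus ATP2A1 was −1.89, −0.45 and 0.50 in pigs 1, 2 and 3, against −0.85 to 0.63 in the saline pigs. Dilution and fewer slow fibres cannot be told apart, since 1 gene below that level is too few. A response of slow fibres to the adjuvant itself also stays open and was not tested. For the fall of oxidative phosphorylation genes in muscle (list median −0.71) dilution stays open too and was not weighed.

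In lymph node, 8 genes of resident macrophages (CD163, MARCO, VSIG4, SIGLEC1, MRC1, C1QA, C1QC and FOLR2) had a median of −1.93, −0.62 and −3.21 in pigs 1, 2 and 3. The set was put together after the results were seen. By the probe sets used FOLR2 alone passed (adjusted p = 0.0307), and VSIG4 passed by its other probe sets (0.019 and 0.0452). Dilution by incoming cells predicts an equal fall of matrix genes, and the macrophage minus matrix median averaged −1.77 ± 1.37 (SD, n = 3), below the saline pigs in each adjuvant pig. Fewer myeloid cells of every kind would lower general myeloid genes as much, and the resident minus general myeloid median averaged −1.89 ± 1.19. The general myeloid set was also put together after the results were seen. Its genes changed by −0.54 to 0.19 and the resident genes by −2.73 to −1.29. The choice of members may itself have given this difference and the one from matrix genes. No conclusion is therefore drawn from either, and dilution stays open. Less sinus tissue in the pieces taken stays open, since LYVE1, PDPN and CCL21, used for lymphatic endothelium, were lower too. The mean of their medians was −1.15, though of the 3 PDPN alone passed. These 3 were chosen after the results were seen from 7 lymph node stroma genes, of which 2 rose when adjusted over the list alone. PDPN is also a gene of reticular cells, so less sinus tissue cannot be told from a change in other stroma. A loss or a changed state of resident macrophages after the adjuvant stays open and was not tested.

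In the muscle of pig 1, type I interferon-stimulated genes had a median of 0.23, against 2.80 and 2.59 in pigs 2 and 3. Degraded RNA in pig 3 leaves the contrast of pigs 1 and 2 as it is, and degradation that differs between these would set their 3' to 5' controls apart. For actin these were 3.28 and 3.29 (pig 1 minus pig 2 −0.012), where the saline pigs ranged from 2.96 to 3.26, and those of GAPDH and EF1A also differed by less than the saline range. Unexposed or mislabelled tissue would leave other genes at the saline level, yet 771 other probe sets called higher without pig 1 had a median of 0.84 in pig 1, where the saline pigs lay between −0.06 and 0.04. A smaller share of exposed tissue would keep about the same share of the rise in both sets of genes, and on the linear scale pig 1 kept a median of 1.63% for interferon genes against 48.1% for the others (quartiles 24.5% and 74.1%). The 771 were chosen by pigs 2 and 3 against these same saline pigs, which narrows the saline range and can lower its mean. Part of the 0.84 and of the 48.1% may come from that choice, and how much was not tested. Interferon-responsive probe sets outside the lists may also remain among the 771. The design gives no biological factor that sets pig 1 apart, so no biological explanation was tested.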

How the results depend on the processing

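The alternatives for the list test of the difference between tissues were added after the results were seen, and all other alternatives were planned. Counts of changed probe sets stayed within 1.5 times with weakly expressed probe sets dropped (973 in muscle, 1366 in lymph node, 1194 for the difference), with arrays centred (961, 1242, 1121), with quantile normalization repeated (940, 1247, 1206), with a trend (833, 1324, 1103) and with a robust prior (969, 1266, 1136). With array weights they rose to 2402, 2256 and 2288, and the cause was not tested. With 1 probe set per gene, which tests fewer probe sets, lymph node had 525 and the difference 624. With the 2-fold minimum, stricter by construction, 572, 364 and 750 passed. The fit of all 12 arrays gave 3322 in muscle and 561 in lymph node without a block, and 3323 and 545 with the pig as a random block, so the block itself moved these counts little. Without a block this fit has the same log2 changes as the separate fits. Its counts therefore moved through the estimate of spread, which it pools over both tissues and more arrays. The difference gave 877 with the pig as a fixed block and 1497 with a random block. Leaving out each pig gave 35 to 1098 in muscle, 141 to 1677 in lymph node and 130 to 1226 for the difference, with the lowest without pig 4 in all of them, and 0 to 87 probe sets called the same way in both tissues. A group then keeps 2 arrays, assumed to vary like the others.

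Of the called lists, 0 passed in muscle, in lymph node or for the difference with an estimated correlation. In lymph node 5 of 12 passed with fry, 5 without weakly expressed probe sets and 7 with the mean of a gene's probe sets, and the cause was not tested. With fry, which compares no list with other genes, the muscle calls for type I interferon-stimulated genes (adjusted p = 0.143), interferon-gamma-induced genes (0.0515), skeletal muscle contraction (0.193), matrix (0.143), stress (0.13) and cytokines (0.193) were lost, and lymph node stroma (0.00878) and reference genes (0.00986) were gained. In lymph node fry lost monocyte and macrophage markers (0.417), T cell markers (0.163), antigen processing (0.0559), NK markers (0.0559), complement (0.225), skeletal muscle contraction (0.163) and glycolysis (0.126). Leaving out each pig gave 13 to 16 lists in muscle, 6 to 14 in lymph node (6 without pig 1, 7 without pig 6) and 9 to 14 for the difference. No list and no named gene reversed its direction past the threshold. Named genes were followed through centring, repeated quantile normalization, the trend, the robust prior, array weights, the random block and leaving out each pig. Of the 68 muscle and 62 lymph node named genes that changed, 64 and 30 passed in each of these that kept all pigs. In all of these alternatives 6 and 7 passed, as did all 10 named for the difference. Those 10 were chosen for their smallest p in the same data, so their share cannot be compared with that of the tissue genes. The other alternatives, the 2-fold minimum among them, were not applied to named genes. The fit of all 12 arrays with the pig as a random block ended 31 calls of named genes in lymph node and 0 in muscle. That fit also pools the spread of the tissues, and the part of the block in these losses was not tested. How far signal over background limits weakly expressed genes was not tested beyond the filter on them.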

Other observations

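The examples below were chosen only after the results were seen, and no test beyond the planned ones was run on them.

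Some genes were called in opposite directions in the tissues. LIPA, the lysosomal acid lipase, changed by 1.74 in muscle and −0.72 in lymph node (difference 2.46, adjusted p = 0.00085), with its other probe set at 1.20 and −0.61. NPL, an enzyme of sialic acid breakdown, changed by 2.00 and −1.14 (difference 3.13, adjusted p = 0.00119), and GLB1, the lysosomal beta-galactosidase, by 0.62 and −0.43 (difference 1.04, adjusted p = 0.00415). DSE, an enzyme of dermatan sulfate synthesis, changed by 1.23 and −0.85 (difference 2.08, adjusted p = 0.00085).

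Other genes rose in both tissues. KYNU, an enzyme of tryptophan breakdown, rose by 2.69 in muscle and 0.86 in lymph node, PGD, of the pentose phosphate pathway, by 1.54 and 0.92, and CD40, the costimulatory receptor of antigen-presenting cells, by 0.92 and 0.74. TSPO, a mitochondrial protein of activated macrophages, rose by 1.81 and 0.83, and LMNA, a nuclear lamin, by 1.30 and 1.02. The difference between tissues passed for none of these 5 genes (adjusted p = 0.132, 0.323, 0.76, 0.0636 and 0.761, in the order given).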
